A study of Mus musculus with 10 samples.

How the data were processed

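The 10 libraries were GFP+ and GFP- tumour cells sorted from 5 mouse MPNST allograft models, 1 library of each population per model. Per the labels, fresh tumours were dissociated with collagenase, non-tumour host cells and dead cells were excluded by flow cytometry, and total RNA of the sorted cells went into Illumina libraries. Per the submitters' processing notes, reads were handled with STAR 2.4.2.8 and the mouse build mm10. The gene annotation, the library kit and its strand setting are not given in the sources used here.

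The deposited values are raw read counts per gene, not normalized, with 46517 genes in each of the 10 tables. Each table has the layout of STAR's gene counts: a gene identifier, a count without regard to strand, and 1 count for each strand setting. The count for the second strand setting was used, because it took 96.9% to 97.1% of the stranded gene reads in every library. Reads with several genomic positions are summed apart in such tables (5.99% to 9.74% of reads), so genes with near-identical copies are counted low and are uncertain. The 4 summary lines (unmapped, multiply mapped, outside genes, ambiguous), 21.3% to 24.3% of the reads, were left out of library sizes and tests. Gene symbols and coordinates came from GENCODE vM21, which is built on the assembly called mm10 in the notes; 46005 identifiers matched and 512 did not. No 2 libraries were identical.

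Library totals in genes were 15978673 to 22082207 reads, and 25762 genes had a read in at least 1 library. Differences of genes at a few reads per library rest on counting noise as well as on the spread of pair differences between tumours. The share of each was not measured. Levels are given as CPM with the SD over 5 libraries of a population.

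The main test followed the series' design text, which states a paired comparison. It was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter (13986 genes kept), the tumour model as a block and GFP+ minus GFP- as the tested coefficient, two-sided, called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors on the log2 scale were derived from the F statistic. The biological coefficient of variation was 0.196. The letters pair the samples, since same-lettered libraries come from the same tumour model. As a check, deviations from the population means correlated at 0.628 to 0.867 within pairs, and each library correlated best with its own pair. The 5 models are taken as the replicates, and whether each model stands for 1 animal is not given in the sources used here.

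Gene lists (39) were fixed with their members before the data were examined, as were the tests, the main design, all alternatives except 3 and the rule for naming genes. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 34 lists, with fry and with camera at an estimated correlation beside it. For each pair the mean log2 difference over a list was taken from log2 CPM with a prior count of 2, and an exact two-sided sign-flip test over 5 pairs, whose smallest p is 0.0625, was applied. The rule for naming genes took the 10 smallest p, since no gene passed, the 5 smallest p in each direction, up to 4 members with the smallest p of each called list and of the Schwann lineage, neural crest and progenitor, DNA replication and mitosis lists, and the 11 genes Nes, Hbegf, Esr1, Mki67, Sox10, S100b, Nf1, Trp53, Cdkn2a, Ptprc and Pecam1. Other list members were named by smallest p, and any further gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here.

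The alternatives were a fit without the block, RLE size factors, library totals only, no filter on low counts, a stricter filter (at least 1 CPM in 5 libraries), leaving out each pair, DESeq2 1.42.0 with the block, limma voom with sample quality weights, leaving out mitochondrial, haemoglobin and ribosomal protein genes, a test against a 2-fold change, camera with an estimated correlation, and lists without shared members. The edgeR likelihood-ratio test, robust quasi-likelihood and unstranded counts were added after seeing the data.

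The pipeline was tested on simulated counts drawn for the 13986 genes with 200 changed genes, all above an average log2 CPM of 1. The quasi-likelihood test recovered 81% of genes changed 2-fold and 96% of those changed 4-fold, and 9.14% of its 197 calls were false. DESeq2 recovered 89% and 98%, and 19.2% of its 239 calls were false. A list planted at a log2 change of 0.5 was called and 0 of 24 lists without a planted gene were. The simulated genes were independent of one another, unlike the genes of a real list. Each planted change was also the same in every pair, whereas real differences varied between pairs. The recovered shares are therefore not the power of the tests in the real data. Reads of the transgene itself were not analysed here.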

Results

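RNA was sequenced from 10 libraries of sorted tumour cells from mouse malignant peripheral nerve sheath tumours (MPNST), a sarcoma of the Schwann cell lineage, grown as allografts. Each of 5 allograft models, lettered A to E, gave 1 library of GFP+ cells and 1 of GFP- cells, so that the 2 populations of a model form a pair. In the series' terms, GFP+ cells express the CGD transgene and GFP- cells do not. The labels do not expand CGD. The genes Nes, Hbegf and Esr1 were followed as mouse relatives of the parts of a published Nestin-driven transgene, a reading that the labels do not state. Per the labels, non-tumour host cells and dead cells were gated out by flow cytometry before the sort. The libraries held 15978673 to 22082207 reads in genes and 18693 to 20454 genes with a read. Genes with a read were more numerous in GFP+ cells in 5 of 5 pairs (19797 ± 412 against 19387 ± 525, SD, n = 5 each; exact sign-flip p = 0.0625, the smallest that 5 pairs allow). Reads outside genes took 10.2% in GFP+ and 9.51% in GFP- cells and were higher in 4 of 5 pairs (exact sign-flip p = 0.188).

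Libraries of the same tumour model were more alike than libraries of the same sorted population. The Spearman correlation across genes was 0.970 to 0.992 between the 2 populations of a pair. It was 0.891 to 0.966 between libraries of the same population from different pairs. Principal components 1 and 2 held 40.1% and 23.9% of the variance. On these components the libraries of models B and D lay together, those of A and E lay in another part of the plot, and those of C lay apart. Genes are not independent replicates, so these values describe the libraries and carry no test. The pairs differed in how far apart their populations lay: 1551 genes differed by more than 2-fold in pair B, 1109 in pair D and 562 in pair C.

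**Figure D1:**
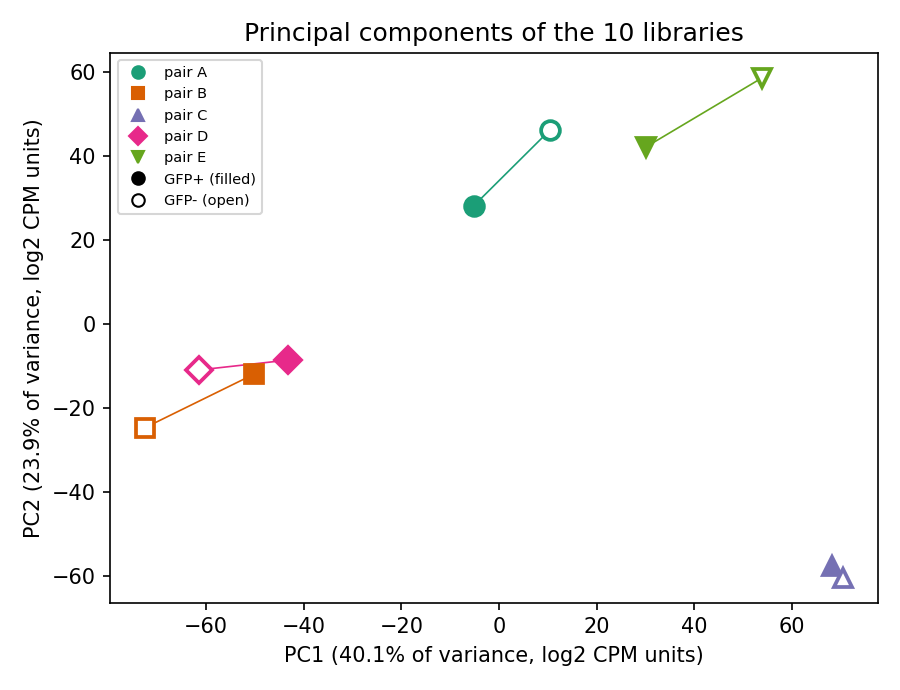
Principal components of log2 CPM (read counts scaled to a common library total) over the tested genes, component 1 on the x axis (40.1% of variance) and component 2 on the y axis (23.9%). Filled marks are GFP+ libraries, open marks GFP- libraries, and a line joins each pair; models B and D lie near each other on the left, A and E at the top, and both libraries of C lie apart at the lower right.

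The comparison of GFP+ with GFP- cells asks which genes differ between transgene-expressing and non-expressing cells of the same tumour model. Among the genes with the smallest p, Sox10, Plxnb3 and Gjc3 had higher values in GFP+ cells. Sox10, the transcription factor that specifies Schwann cells, stood at 35.8 ± 46.4 CPM in GFP+ cells and 2.64 ± 3.24 CPM in GFP- cells (SD, n = 5 each), a log2 difference of 3.61 (SE 0.40). Plxnb3, a semaphorin receptor, differed by 3.61 (SE 0.34) and Gjc3, a connexin of myelinating glia, by 3.20 (SE 0.45). All 3 genes were higher in GFP+ cells in pairs B, C and D. In pairs A and E they had few reads: 1 and 3 against 0 for Plxnb3, 2 and 2 against 0 for Gjc3, and 2 against 1 and 9 against 0 for Sox10. Nes, which encodes the intermediate filament nestin of neural progenitors, stood at 94.3 ± 75.6 CPM in GFP+ and 44.3 ± 36.4 CPM in GFP- cells (SD, n = 5 each), a log2 difference of 1.20 (SE 0.29), and was higher in 4 of 5 pairs.

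None of these single-gene differences passed edgeR's quasi-likelihood test across all genes that its main filter kept. With edgeR's quasi-likelihood test and the pair as a block, 0 of 13986 genes had a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 1257 genes, 769 higher and 488 lower in GFP+ cells, against 699 expected with no difference. Without pair B there were 793 such genes and without pair D 796. DESeq2 with the same block called 204 genes (153 higher, 51 lower) and edgeR's likelihood-ratio test, added after the data were seen, 206 (154 higher, 52 lower), with 168 called by both. The calls of DESeq2 included Sox10 (adjusted p = 4.91e-15), Plxnb3 (1.68e-08), Gjc3 (5.03e-05) and Nes (0.00164), so their verdict depends on the tool. On the simulated counts DESeq2 made more false calls than edgeR's quasi-likelihood test. Over all tested genes, 1369 (9.79%) had the same direction in 5 of 5 pairs, where chance alone gives 6.25% on average. Genes are not independent of one another, and whether this share exceeds chance was not tested. Pgm5, Crmp1, Lgi4 and Myo5b, named here after their values were seen, were among 13 genes at least 2-fold higher in GFP+ cells in every pair, and 0 genes were at least 2-fold lower in every pair. Some of these pair values rested on few reads. In pair E, Mmp15, also among the 13, had 8 reads against 0, and Lgi4 had the same log2 difference of 2.24. Myo5b had the pair E difference of Sox10, 2.38, which came from 9 reads against 0.

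The gene with the smallest p was Plxnb3 (ENSMUSG00000031385, mm10 chromosome X, 73757090 to 73772514), with an adjusted p of 0.123 by edgeR. Sox10 (ENSMUSG00000033006, chromosome 15, 79154908 to 79165240), Greb1 (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886), Uchl1 (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234) and Elfn1 (ENSMUSG00000048988, chromosome 5, 139907943 to 139974722) each had an adjusted p of 0.183. Greb1, known as an oestrogen-induced gene, differed by a log2 of 1.46 (SE 0.17). Uchl1, a neuronal ubiquitin hydrolase, differed by 1.33 (SE 0.16), Elfn1 by 2.06 (SE 0.26) and the membrane metalloprotease gene Mmp15 by 2.17 (SE 0.30), each higher in 5 of 5 pairs. Among genes lower in GFP+ cells, the smallest p belonged to Crybg3 (log2 -0.61, SE 0.09), the actin regulator Phactr1 (-0.55, SE 0.08), Sned1 (-1.05, SE 0.15), the interferon-induced Ifitm1 (-1.07, SE 0.17) and Egfl6 (-1.24, SE 0.20). These 5 genes were lower in GFP+ cells in 5 of 5 pairs, at adjusted p of 0.199 for Crybg3, Phactr1 and Sned1 and 0.230 for Ifitm1 and Egfl6 by edgeR.

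The level of Sox10 depended on the tumour model. It was 17.1 CPM in GFP+ cells against 1.63 in GFP- cells of pair B, 52.6 against 7.65 in pair C and 112 against 3.69 in pair D. In pair A it was 0.11 against 0.05 CPM and in pair E 0.43 against 0, levels at which a difference was hardly detectable at this depth. Nes was 88.4 CPM in GFP+ and 97.2 in GFP- cells of pair A, and the pair log2 differences were 1.999 in B, 1.00 in C, 1.74 in D and 1.39 in E. Hbegf, a growth factor of the EGF family, differed by 0.47 (SE 0.22) and was higher in 3 of 5 pairs; without pair E the difference was 0.21. Esr1, the oestrogen receptor alpha gene, differed by -0.41 (SE 0.38), and by -0.10 without pair B, -0.18 without pair C and -0.62 without pair D. Adjusted over the list alone, 1 of these 3 transgene-related genes passed (Nes), against 0 over all genes.

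**Figure D2:**
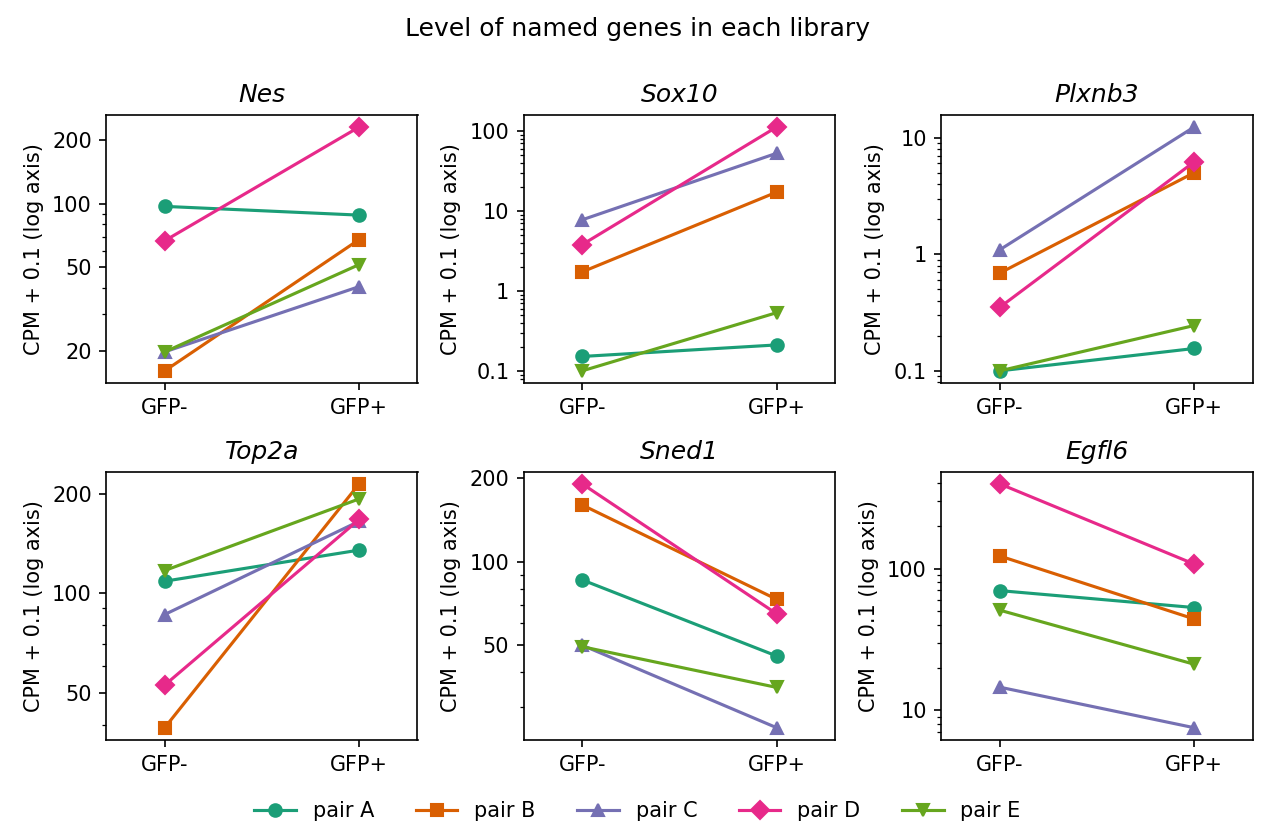
Level of 6 genes in CPM plus 0.1 on a log y axis in the GFP- and GFP+ library of each tumour model, with a line joining the 2 libraries of a pair. Sox10, Plxnb3 and Top2a were higher in GFP+ cells in all 5 pairs, Nes in 4 of 5 pairs, and Sned1 and Egfl6 were lower in all 5.

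The tumour suppressor genes lost or mutated in MPNST differed little. Nf1, the RAS regulator, stood at 61.4 CPM in GFP+ and 63.0 in GFP- cells (log2 -0.0044, SE 0.11), Trp53 at 201 and 202 CPM (log2 0.0055, SE 0.10), both with a sign that changed under other scalings or filters, and Cdkn2a at 422 and 464 CPM (log2 -0.13, SE 0.11), or -0.03 without pair A. S100b, a Schwann cell calcium-binding protein gene, was too low to be tested, at 2.93 CPM or less in every library.

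Of 39 gene lists fixed beforehand, 34 had at least 5 tested genes, and camera with a preset correlation of 0.01 called 9 of them, 5 higher and 4 lower in GFP+ cells. With the correlation between genes estimated from the data, camera called 0 of the 34, with 2 lists at an unadjusted p under 0.05. The rotation test fry called 0 lists for a change in 1 direction, with 4 at an unadjusted p under 0.05, and 6 for a change in either direction. These 6 were the Schwann lineage, neuronal, quiescence, p53 target, neural crest and progenitor, and YAP and TEAD target lists. The mitosis, interferon response and DNA replication lists were not among them. Over the 5 pairs, the exact sign-flip p was 0.0625, the smallest possible, for the Schwann lineage, mitosis and neuronal lists. It was 0.125 for the interferon response and fibroblast lists and 0.188 for DNA replication. For hypoxia and glycolysis and for complement it was 0.25, and for quiescence 0.375.

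Schwann lineage genes lay higher as a group: 16 of 18 tested genes were higher and 2 lower in GFP+ cells, with a median log2 difference of 0.98 (adjusted p = 1.09e-10 by camera). The list was closest to the threshold otherwise, at adjusted p = 0.0613 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 5 passed and 13 did not. These 5 were Sox10, the neural crest factor Foxd3 (log2 1.38, SE 0.38), the neuregulin receptor Erbb3 (2.24, SE 0.63, and 1.44 without pair D), Pou3f1 (1.95, SE 0.56), a factor of promyelinating Schwann cells, and the small heat shock protein gene Cryab (0.94, SE 0.27). The list mean was higher in 5 of 5 pairs, from 0.34 in pair A to 1.59 in pair D, with a mean of 0.90 ± 0.46 (SD, n = 5 pairs). Its exact sign-flip p was 0.0625, the smallest that 5 pairs allow. In pair D, where the list differed most, Xist also differed (103 CPM in GFP+ against 2.82 in GFP- cells). Without pair D the list median was 0.66 (adjusted p = 2.76e-09 by camera). The neuronal list had 6 of 8 genes higher (median 0.88, adjusted p = 2.27e-06 by camera), and adjusted p = 0.286 with an estimated correlation. Uchl1 and the neurofilament genes Nefl (1.12, SE 0.29) and Nefm (1.18, SE 0.35) passed adjusted over the list alone, 3 genes in all, against 0 over all genes.

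Genes of cell division were also higher in GFP+ cells. All 27 genes of the mitosis list were higher, with a median log2 difference of 0.76 (adjusted p = 2.73e-30 by camera), and adjusted p = 0.445 with an estimated correlation. Over all genes 0 passed, and adjusted over the list alone 24 passed, among them the spindle gene Prc1 (1.15, SE 0.20), the kinase genes Aurkb (1.18, SE 0.28) and Aurka (0.94, SE 0.23) and the topoisomerase gene Top2a (1.18, SE 0.28). Top2a stood at 173 ± 30.4 CPM in GFP+ and 81.5 ± 34.3 CPM in GFP- cells (SD, n = 5 each). Mki67, the proliferation marker, differed by 0.67 (SE 0.25) and was higher in 4 of 5 pairs, and by 0.44 without pair B. The size of the difference varied between pairs: the list mean was 0.05 in pair A, 1.74 in B, 0.49 in C, 1.26 in D and 0.51 in E. All 28 DNA replication genes were higher, with a median of 0.37 (adjusted p = 5.28e-10 by camera), and adjusted p = 0.491 with an estimated correlation. None of the 28 passed over all genes or adjusted over the list alone, where Chaf1a (0.43, SE 0.13), Cdc45 (0.36, SE 0.12), Cdc6 (0.71, SE 0.26) and Rrm2 (0.71, SE 0.28, and 0.43 without pair B) had the smallest p. Without pair B the median of the replication list was 0.18. Its list mean was -0.10 in pair A, 1.05 in B, 0.25 in C, 0.66 in D and 0.06 in E (exact sign-flip p = 0.188).

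The list of quiescence genes and cell-cycle inhibitors had 16 of 22 genes lower (median log2 -0.13, adjusted p = 0.009997 by camera), and adjusted p = 0.445 with an estimated correlation. Its median was -0.03 without pair B and -0.20 without pair A. Adjusted over the list alone 3 passed, against 0 over all genes: the kinase inhibitor gene Cdkn1b (-0.32, SE 0.08) and Txnip (-0.51, SE 0.13) were lower, and Cdkn1a (0.50, SE 0.12), which encodes p21, was higher in 5 of 5 pairs. Hypoxia and glycolysis genes were higher in 24 of 25 cases (median 0.20, adjusted p = 0.000612 by camera), and adjusted p = 0.650 with an estimated correlation. None passed over all genes or adjusted over the list alone, and the growth factor gene Vegfa (0.26, SE 0.07) had the smallest p. Pair A went against the others in this list, with a mean of -0.45, and without it the median was 0.37. Without pair C the list was not called (median 0.11, adjusted p = 0.116 by camera), and without the block it was called at a median of 0.09 (adjusted p = 0.0183).

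**Figure D3:**
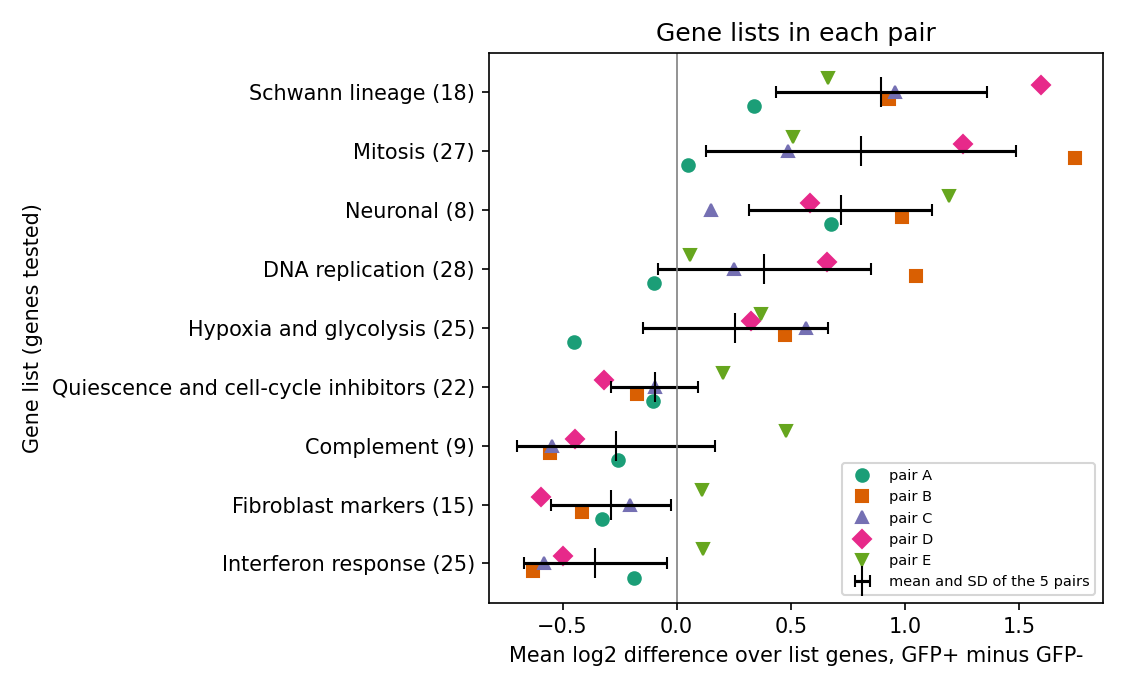
Mean log2 difference, GFP+ minus GFP-, over the tested genes of the 9 lists called by camera (x axis), with 1 coloured mark for each pair and black bars for the mean and SD of the 5 pairs. Schwann lineage, mitosis and neuronal genes were higher in all 5 pairs, and the lists lower in GFP+ cells were each lower in 4 of 5 pairs, with pair E above 0.

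Interferon response genes were lower in GFP+ cells: all 25 tested genes were lower, with a median log2 difference of -0.34 (adjusted p = 3.27e-13 by camera), and adjusted p = 0.445 with an estimated correlation. None passed over all genes or adjusted over the list alone. The antiviral gene Mx1 (-0.92, SE 0.22), Mx2 (-0.82, SE 0.24), annotated as a polymorphic pseudogene, and Ifit3 (-0.53, SE 0.15) were among those with the smallest p. All 3 were lower in 5 of 5 pairs, but in pair E the differences of Mx2 and Ifit3 were only -0.04 and -0.0074. Ifit3 has a near-identical neighbouring copy, so its count is uncertain. The list mean was lower in 4 of 5 pairs and 0.12 in pair E.

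Fibroblast markers were lower in 13 of 15 cases (median -0.35, adjusted p = 0.0115 by camera), and adjusted p = 0.445 with an estimated correlation. These genes were abundant in the sorted cells: their summed level was 5330 ± 3795 CPM in GFP+ and 6054 ± 3250 CPM in GFP- cells (SD, n = 5 each). Much of this came from 1 gene, Dcn, at 3061 ± 3996 and 3034 ± 3718 CPM. None passed over all genes or adjusted over the list alone, where Pdgfra (-0.51, SE 0.13) had the smallest p and Igf1 (-1.23, SE 0.56, -0.78 without pair D and -1.97 without the block) was lower in pairs B, C and D and higher in A and E. Its median was -0.23 without pair B and -0.20 without pair D. Without the members it shares with other lists, the fibroblast list was not called (median -0.32, adjusted p = 0.154 by camera). Complement genes were lower in 6 of 9 cases (median -0.37, adjusted p = 0.0122 by camera), and adjusted p = 0.445 with an estimated correlation. Adjusted over the list alone 3 passed, against 0 over all genes: the protease genes C1ra (-0.85, SE 0.17) and C1s1 (-0.86, SE 0.21), each with a close paralogue beside it, and Cd55 (-0.37, SE 0.12). The complement call was lost without pair B (median -0.29, adjusted p = 0.122 by camera) and without pair C (-0.40, adjusted p = 0.123).

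The neural crest and progenitor list was not called by camera: 11 of 20 genes were higher and 9 lower (median 0.03, mean 0.25, adjusted p = 0.291 by camera). The list mean was higher in 5 of 5 pairs, from 0.11 in pair D to 0.67 in pair A (exact sign-flip p = 0.0625). For a change in either direction the list was called by fry (adjusted p = 0.0429). Over all genes and adjusted over the list alone 0 passed, and the smallest p belonged to Nes, Nr2f2 (-0.28, SE 0.08), Pax6 (2.82, SE 0.94) and Sox11 (1.12, SE 0.40). The value for Pax6 depended on the model, at 0.65 without the block and 5.01 by DESeq2, and its pair D difference was 0.10. That for Sox11 was 0.71 without the block. The other 24 lists that camera did not call had adjusted p from 0.0910 to 0.762 by camera. Of these, fry called YAP and TEAD targets (adjusted p = 0.0399) and p53 targets (adjusted p = 0.0405) for a change in either direction. Collagens and interstitial matrix had a median of -0.07, basement membrane -0.07, mesenchymal transition genes -0.07 and MPNST driver and receptor genes -0.06. YAP and TEAD targets had a median of -0.03 and a mean of 0.10, RAS and MAPK output genes a median of 0.05, WNT targets and antagonists 0.08, Notch pathway genes 0.06, Hedgehog pathway genes -0.13 and TGF-beta and BMP targets -0.06. Immediate-early and heat shock genes, which tissue dissociation induces, had a median of -0.16 and MHC class I genes -0.13. Medians were 0.05 for p53 targets, 0.04 for the unfolded protein and ATF4 response, -0.05 for cholesterol synthesis, -0.04 for cytosolic ribosomal proteins, -0.01 for nuclear oxidative phosphorylation genes and 0.07 for mitochondrially encoded genes. The cytokine and chemokine list had a median of 0.13 and a mean of -0.19. Adjusted over the list alone, 2 p53 targets (Sesn2 and Cdkn1a, both higher), 1 YAP and TEAD target (Nt5e, higher) and 1 cytokine gene (Cxcl5, lower) passed, and no other gene of these lists did. Some of these lists were called by camera under other settings: MPNST driver and receptor genes with no filter on low counts and without pair E, cytosolic ribosomal proteins without pair A, B or D, and immediate-early and heat shock genes without pair B or E. Collagens and interstitial matrix were called without pair A. Epithelial markers, WNT targets and antagonists, cholesterol synthesis, nuclear oxidative phosphorylation and mitochondrially encoded genes were called without pair D. MHC class I, cytokine and chemokine genes and TGF-beta and BMP targets were called without pair E.

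Markers of blood and vessel lining cells were low. Macrophage markers summed to 42.2 ± 12.1 CPM in GFP+ and 49.6 ± 26.3 CPM in GFP- cells, and endothelial markers to 19.6 ± 9.01 and 20.6 ± 14.1 CPM (SD, n = 5 each). Their median log2 differences were -0.03 and 0.09, with means of 0.09 and -0.16. Pericyte and smooth muscle markers summed to 387 ± 181 CPM in GFP+ and 555 ± 368 CPM in GFP- cells (SD, n = 5 each), and 7 of 8 tested genes were lower in GFP+ cells (median -0.37, adjusted p = 0.124 by camera). Pdgfrb, which is not specific to pericytes, gave most of this level (226 ± 97.2 and 374 ± 264 CPM). The list was called with no filter on low counts and without pair C or E. Epithelial markers had a median of 0.30 over 7 genes and skeletal muscle markers -0.14 over 5, with a mean of 0.15. In the skeletal muscle list only Ttn, higher in GFP+ cells, passed adjusted over the list alone. Neutrophil, lymphocyte and erythroid lists had 0 tested genes and the adipocyte list 1, and lymphocyte markers summed to 0.94 CPM or less in every library. The leukocyte gene Ptprc reached at most 0.45 CPM and the endothelial gene Pecam1 1.31 CPM, both too low to be tested.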

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

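The test of the opposite strand was chosen after the data were seen, and the search for outlying values followed a fixed rule. In 108 groups of 5 values, library measures within a population or pair differences of named genes and tested lists, 8 held a value far from the other 4, against 5.4 expected, since chance marks about 1 group in 20. The number after each item is the gap to the nearest value as a share of the range, which marks an item above 0.71.

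Among pair differences of gene lists, hypoxia and glycolysis genes were lower in GFP+ cells of pair A (mean log2 -0.45) and higher in the other 4 pairs (0.32 to 0.57; gap 0.760). Complement genes were higher in pair E (0.48) and lower in the other pairs (-0.56 to -0.26; gap 0.712). Cytosolic ribosomal protein genes were lower in pair A (-0.75), against -0.01 to 0.27 in the others (gap 0.718). Among single genes, the Mmp15 difference was smallest in pair A, at 1.36 against 2.07 to 2.24 (gap 0.8075). The Pdgfra difference was -0.05 in pair E against -0.71 to -0.56 in the others (gap 0.769), and that of Cd55 was -0.76 in pair B against -0.36 to -0.21 (gap 0.722). Among the libraries, GFP+ cells of pair E had 20722994 reads in genes against 17994973 to 18779225 in the other GFP+ libraries (gap 0.7125). GFP+ cells of pair C had 1.19% ambiguous reads against 1.05% to 1.09% (gap 0.736).

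Counts for the opposite strand, which no comparison above used, gave 2 genes with an adjusted p under 0.05 by edgeR among 3276 tested, and 246 at an unadjusted p under 0.05. Both were named after their values were seen. Fxyd3 (mm10 chromosome 7, 31068172 to 31076704) was higher in GFP+ cells (log2 2.51, adjusted p = 0.0234) and Mterf4 (chromosome 1, 93299211 to 93305915) lower (-1.12, adjusted p = 0.0278). Each overlaps a gene on the other strand, Lgi4 for Fxyd3 and Sned1 for Mterf4, whose own log2 differences were 2.50 and -1.05, so reads from the neighbour's strand enter both.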

How the results depend on the processing

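The likelihood-ratio test, robust quasi-likelihood and unstranded counts were added after seeing the data. The count of 0 called genes by edgeR's quasi-likelihood test stayed 0 in 14 of 17 alternatives, with 66 to 1477 genes at an unadjusted p under 0.05 in those. It was 47 with no filter on low counts (37 higher, 10 lower), 204 with DESeq2 (153 higher, 51 lower) and 206 with the likelihood-ratio test (154 higher, 52 lower); the cause was not tested. Without the replicate block, which sets the paired libraries against each other without regard to tumour model, 0 genes were called, 190 had an unadjusted p under 0.05, 8 lists were called and the complement call was lost (median -0.68, adjusted p = 0.210); no other call changed with the pairing, but the hypoxia and glycolysis median was 0.0906 against 0.1982. The 9 called lists became 0 with an estimated correlation and 8 to 15 with 1 pair left out. Of the 117 list values recomputed, 0 changed sign. Of 886 values of 56 named genes, 10 changed sign, all of Nf1 and Trp53 near 0. Nf1 was 0.0276 with library totals, 0.0214 by voom and -0.1015 to 0.0746 with 1 pair left out. Trp53 was -0.0075 without the block, -0.0106 with no filter, -0.0035 by voom and -0.0526 to 0.0796 with 1 pair left out. DESeq2 put 26 named genes past the threshold, the likelihood-ratio test 25 and quasi-likelihood with no filter on low counts 13. Among those past it by DESeq2 were Sox10, Plxnb3, Gjc3, Nes, Prc1, Top2a, Aurkb, Aurka and Pdgfra. Depth limits genes at a few reads per library, such as Sox10 in pairs A and E.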

Other observations

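Among the tests in this part, those of myelin genes, of markers of other cell types and of Y-linked genes were chosen after the result was seen. The genes that DESeq2 called and the naming rule did not take were looked at after their values were seen. Examples higher in GFP+ cells were the Schwann cell ligand Dhh (log2 3.51, adjusted p = 0.000242 by DESeq2), Lgi4 (2.50, adjusted p = 8.26e-06), Ptprz1 (0.97, adjusted p = 5.30e-05) and Reln (1.16, adjusted p = 0.000394). Lower in GFP+ cells were the muscle kinase gene Mylk (-1.55, adjusted p = 0.000435), the matrix cross-linking gene Lox (-0.70, adjusted p = 0.00303) and Agtr2 (-1.01, adjusted p = 0.00232). They were not drawn from a fixed list and no theme was tested. Dhh was too low for the filter of edgeR's quasi-likelihood test, which none of the other genes in this paragraph passed, and DESeq2 made 19.2% false calls on simulated counts.

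The populations did not differ in the same way in every tumour model. Across genes, which are not independent replicates, the GFP+ minus GFP- differences of pairs B and D correlated at 0.52 and those of pairs A and E at 0.28, while the other pairs of models gave -0.05 to 0.15. Igf1 stood at 539 CPM in GFP- and 128 in GFP+ cells of pair B, 407 and 58.7 in pair D and 60.5 and 16.8 in pair C, but at 17.4 and 25.6 in pair A and 37.3 and 49.4 in pair E.

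The higher Schwann lineage genes had 2 technical explanations to weigh. Mature myelinating Schwann cells in the GFP+ sort would bring their abundant myelin transcripts, but the median log2 difference of 7 myelin genes over pairs B, C and D was 0.12, against 1.31 for the other genes of the list. A general excess of non-tumour cells cannot be told apart. The 37 macrophage, endothelial, pericyte and fibroblast markers had a median of -0.10 (bootstrap 95% interval over genes -0.35 to -0.04). However, the pericyte and fibroblast markers were abundant in both populations, which would hide a small share of other cells. The 14 others were near the floor (median 0.03, interval over genes -0.07 to 0.17, 7 higher). Both intervals resample genes, which are not independent replicates, and do not measure the spread between tumour models. Immature or non-myelinating Schwann cells, which the gate against host cells is meant to remove, stay open as untested, as does a difference between transgene-expressing and other tumour cells, which the design names. In pair D, where the list differed most, Xist also differed, at 103 CPM in GFP+ against 2.82 in GFP- cells, so cells of another source in that library stay open, and without pair D the list median was 0.66.

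The higher mitosis genes were set against gene length and GC content and against the weight of 1 pair. After regression of the log2 differences of 13949 genes on length, GC content and expression, the mitosis median was 0.77, against 0.76 before, and it lay above the medians of all 10000 random lists matched on these properties. With 1 pair left out the lowest median was 0.56, without pair B. Both results argue against these causes as the whole of the pattern. The correlation between its genes was estimated at 0.96 by camera, so the 27 genes act as nearly 1 measurement. A difference between the populations that the design names stays open and was not tested.

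Pairs A and D expressed Y-linked genes and pairs B, C and E Xist, yet the GFP+ library of pair D held 103 CPM of Xist against 2.82 in its GFP- library. Mixing with pair C is argued against: 5 genes of pair C absent from GFP- cells of D were found at a median of 0.0458 of the level that the Xist share of 15.3% would give (upper bound 0.11). For pairs B and E a single gene qualified, at 0.0837 or less, so mixing with them cannot be told apart from other sources. Female host cells would lower Y-linked genes in pair D more than in pair A, but the difference was -0.0614 between medians of -0.64 and -0.58, too small a contrast to decide, so this too cannot be told apart. Y-linked genes were lower in GFP+ cells of both pairs, and Xist expressed by the tumour cells of D themselves was not tested. The GFP+ library of pair E held low levels of Y-linked genes. Eif2s3y was at 1.64 CPM against 0.11 in GFP- cells of E, Ddx3y at 1.35 against 0.11, Kdm5d at 0.92 against 0.22 and Uty at 0.72 against 0.05. Their source was not tested, and low counts of other genes in that library, such as Sox10 and Plxnb3, could share it.

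Other splits of the 10 libraries bear on the counts. Of 100 splits drawn from all splits into 5 and 5, the real one included, 100 called at least the real 0 genes (highest other 9), which any split does, so that this count decides nothing. Of the 100 splits, 16 gave at least the real 1257 genes at an unadjusted p under 0.05 (highest other 2863) and 72 called at least the real 9 lists with the preset correlation (highest other 20), so chance cannot be excluded for either count. These splits parted 1, 3 or 5 pairs, and a pair that is not parted adds nothing in the fit with the block, so the 100 splits held 55 distinct fits. Of these, 9 gave at least 1257 genes and 38 at least 9 lists. Among the 16 splits that part all 5 pairs, which are too few for a share under 0.05, 4 gave at least 1257 genes at an unadjusted p under 0.05 (highest other 1646), 11 called at least 9 lists (highest other 16) and 1, the real one, called at least the 204 genes of DESeq2 (highest other 156). The split with 1646 and 156 genes had the populations of pairs A and E exchanged against those of B, C and D. It was singled out after its values were seen, and its cause was not tested. The split with 2863 genes, more than the real count, parted pairs A, B and D with A exchanged against B and D.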
